A study of Saccharomyces cerevisiae with 14 samples.

How the data were processed

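Rad52 binding was mapped by chromatin immunoprecipitation and sequencing in budding yeast. Rad52 is a recombination protein that gathers at damaged DNA, and the series uses it as a readout of damage that comes from DNA-RNA hybrids. The 14 libraries fall into 8 groups. WT, Sen1-AID, h1D-h2D, h1D-h2D Sen1-AID, h1D-h2D Top1-AID and Gal-HO galactose have 2 libraries each, and Top1-AID and Gal-HO dextrose have 1 each. h1D-h2D was read as the strain without the RNase H genes RNH1 and RNH201, since the design names those genes. AID marks a protein fused to an auxin-inducible degron, which auxin causes to be degraded. Per the labels' protocols, the 11 libraries outside the Gal-HO strain, WT included, received 0.5 µM auxin for 4 h. Gal-HO strains make the HO endonuclease, which cuts the mating-type locus MAT, when grown in 2% galactose. Nothing in the labels states that replicates are separate cultures, so p-values of tests over libraries measure spread between samples. Random placement, the sign test, the McNemar test and tests between sets of regions or genes take regions or genes as units. Their p-values hold no spread between libraries.

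Each file is a list of peaks for 1 library, with chromosome, start, end, name and a score per peak. The score is the authors' unit, and no header or label gives its scale. It was used only to rank peaks within a list, as a percentile. Per the submitters' processing notes, the tools were Bowtie2 and MACS2 and the genome build was sacCer3, and no versions are given. Whether a control library entered the peak calling is not stated. Read depth is unknown for all 14 libraries, so differences in depth between libraries cannot be corrected. The number of peaks per list sets the precision of a share, and exact Clopper-Pearson intervals at 95% cover counting error only.

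Gene positions came from the RefSeq table of the R64 assembly, which is sacCer3, with 6431 genes. Positions are 1-based. All lists together held 7181 peaks, from which peaks on the mitochondrial chromosome were then counted apart. Of 24 locus lists written before the data were examined, 20 were used. Pericentromeres, replication origins, intron-containing genes and the mitochondrial genome as a class were not analysed here. All names of the other lists were found except 1 of 18 cell wall repeat genes. Subtelomeres are the 20 kb at each chromosome end, and long coding genes measure at least 4 kb. Ty retrotransposons were taken as hyphen-suffixed coding loci of at least 4 kb, which gave 34 loci and misses Ty copies with plain names, such as YER160C and YML045W. Lists of 7 a-specific, 4 alpha-specific and 12 pheromone response genes were written after the data were examined.

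The combined mutants, h1D-h2D Sen1-AID and h1D-h2D Top1-AID, were set against the other 7 auxin libraries, since an exact test of 2 libraries against 2 cannot go below p = 0.333. Library means were compared by exact two-sided permutation tests over all 330 splits of 4 against 7. These splits treat replicates of the same strain as independent, so the p-values do not measure spread between strains. Peaks of the 11 libraries were merged where they overlapped by at least 1 bp, and presence per region was tested by Fisher's exact test. For enrichment, the regions shared by all libraries of a group were placed at random within their chromosomes 10000 times, and the smallest p this can give is 0.0002. Agreement between libraries was the Jaccard index, shared over total covered length, with 100000 permutations of the group labels and a one-sided test. Covered length within 50 kb of MAT was tested one-sided over 91 splits. RNase H genotype was tested over 462 splits. The interaction of Sen1 depletion and h1D-h2D was tested over 36 arrangements, for which the smallest p is 0.0556. Adjusted p-values follow Benjamini and Hochberg, with a threshold of 0.05.

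A region new in a mutant had a peak in every library of that group and none in WT. The genes named are the edited loci, the mating-type loci, the galactose genes, the 10 regions per group or comparison with the highest mean score percentile, and up to 4 members of each list. Of the regions that differed between the combined mutants and the others, the 10 with the smallest p in each direction are named, ties ordered by that percentile. Genes outside this rule are named as chosen after their values were seen, and some genes that the rule would name are not reported here. The number of list members covered by a peak, the position of peaks relative to genes and the mating-type gene lists were added after the data were examined. For peak position, each gene overlapped by exactly 1 peak gave the signed distance from gene midpoint to peak midpoint and the reach of the peak past each gene end. The median over genes was taken per library, and the adjusted p covers 48 tests.

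The alternatives were a stricter score limit at the pooled median, lists shortened to the 254 highest-scoring peaks each, peaks within 1 kb joined, repeated loci and chromosome ends left out, a stricter overlap rule, 5 kb bins, circular shifts for random placement, peak midpoints in place of overlap, the replicate number as a block, each combined mutant alone, 10 and 100 kb around MAT, and each library left out in turn. The steps were tested on simulated data. For the regions that differ between the combined mutants and the others, 853 regions were simulated with 200 changed, of which 96.5% passed the unadjusted threshold and 81% the adjusted one, while 0.766% of unchanged regions passed the unadjusted threshold. There, changed regions were nearly always present in a set and nearly never in the other. Libraries were drawn independently, and unchanged regions were as frequent in both sets. The real lists differ in length and replicates resemble each other, so these shares are not their power or error rate. For class enrichment, 0 classes were called among 569 random regions. For the peak position at 74 snoRNA genes, a planted lengthening of 400 bp was recovered as 400 bp. Each single peak was lengthened by that much, so this checks the arithmetic only. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.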

Results

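The libraries mapped peaks of Rad52 immunoprecipitation after RNase H, Sen1 or Top1 was removed, alone or together. The Gal-HO libraries mapped them in a strain that makes HO in galactose. Sen1 is a DNA-RNA helicase, Top1 a topoisomerase, and RNase H digests the RNA of a hybrid. WT libraries held 666 and 617 nuclear peaks, Sen1-AID 731 and 454, h1D-h2D 634 and 578, and Top1-AID 551. The h1D-h2D Sen1-AID libraries held 286 and 305 peaks and the h1D-h2D Top1-AID libraries 282 and 254. Gal-HO galactose gave 544 and 637 peaks and Gal-HO dextrose 637. Peaks covered between 511 kb, or 4.24% of the genome, in h1D-h2D Top1-AID replicate 2 and 1904 kb, or 15.8%, in Sen1-AID replicate 1. Read depth is unknown.

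**Figure D1:**
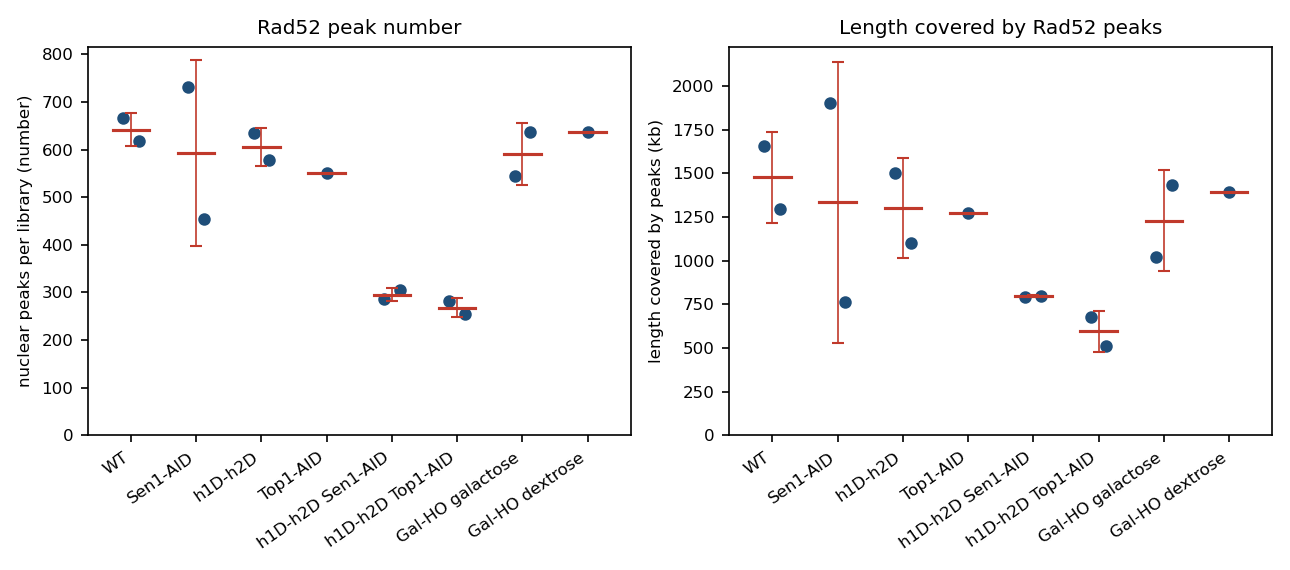
Nuclear Rad52 peaks per library (left, number) and the length they covered (right, kb) in the 8 groups. Points are libraries, red bars are group means and whiskers are 1 SD where a group has 2 libraries; the 4 libraries of the combined mutants hold 254 to 305 peaks and the 7 other auxin libraries 454 to 731.

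The first question was where Rad52 peaks lay in wild-type cells. TEF1 (XVI 699533–702739), ENO2 (VIII 450121–453542) and ADH1 (XV 158751–161801) carried the highest-scoring regions shared by both WT libraries, at mean percentiles of 99.9, 99.8 and 99.6. RPL8A followed at 99.3 and the region of RSC30 and CUP1 at 99.05, then YEF3, TEF2, RPL28, RPL33B and PDC1. Of the 569 regions shared by both WT libraries, 214 overlapped a tRNA gene, where random placement gave 33.2. Ribosomal protein genes were overlapped by 122 regions (random 20.5), snoRNA and snRNA genes by 60 (random 9.07), and glycolytic and translation elongation genes by 19 (random 4.17). For these 4 lists the permutation p was 0.0002, the smallest that 10000 placements can give, with an adjusted p of 0.000941.

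The same 4 lists carried more regions than random placement in all 8 groups, Gal-HO dextrose included. There, 194 of 637 regions overlapped tRNA genes against 32.6 at random, and 119 overlapped ribosomal protein genes against 20.5. Every library was a Rad52 precipitation, and no control is known. So signal at these lists that is not specific to Rad52 cannot be told apart from Rad52 binding. Y prime helicase genes, which lie in chromosome-end repeats, passed the adjusted threshold in h1D-h2D (8 regions, random 2.04) and in Top1-AID (9 regions, random 2.17). Histone genes passed it in Top1-AID (5 regions, random 0.912). Over 160 tests of a list in a group, 37 showed more regions than random and 8 fewer. Long coding genes were overlapped less often than at random in every group except the combined mutants, as in WT with 64 regions against 86.9 (adjusted p 0.0231).

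The main question of the series was what happened to Rad52 peaks when more than 1 of these activities was removed. By a count of covered genes added after the data were examined, peaks at ribosomal protein genes fell from 127 ± 13.4 genes covered of 138 (SD, n = 7) to 62 ± 6.73 (n = 4) in the combined mutants. Covered tRNA genes fell from 222 ± 24.1 of 275 to 107 ± 10.3, and snoRNA and snRNA genes from 74.4 ± 2.99 of 82 to 48.3 ± 2.99. Histone genes fell from 8 ± 0.577 of 10 to 2 ± 1.41, and Y prime helicase genes from 6.71 ± 0.951 of 8 to 1 ± 2. In each of these lists all 4 combined-mutant libraries lay below all 7 others. The exact p was 0.00303, the smallest possible, with an adjusted p of 0.00673 over 20 lists. The 4 libraries include replicates of the same strain, so these p-values do not cover spread between strains. Ty elements were covered at 13.8 ± 4.99 and 15.6 ± 3.82 of 34 loci, a difference within the spread (exact p adjusted 0.494). With every list shortened to its 254 highest-scoring peaks, the difference at tRNA genes was 28.3 in the opposite direction.

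**Figure D2:**
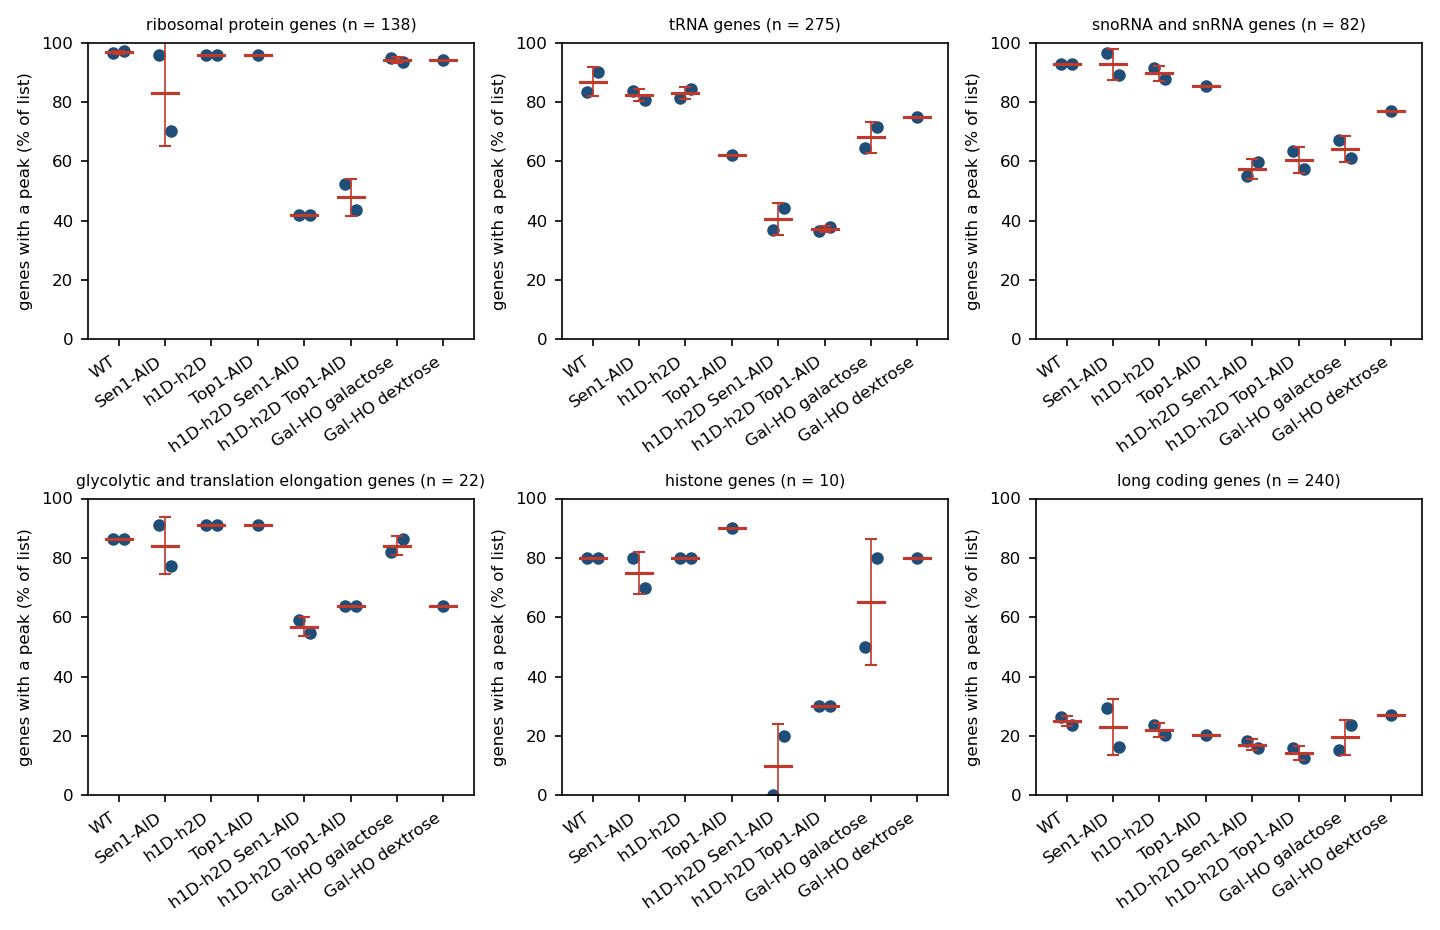
Share of the genes of 6 lists that carried a Rad52 peak (percent of the list, axis from 0 to 100%) in the 8 groups. Points are libraries, red bars are group means and whiskers are 1 SD where a group has 2 libraries; for ribosomal protein genes the combined mutants average 62 of 138 genes and the other auxin libraries 127.

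In total, the combined mutants had 282 ± 21.0 peaks (SD, n = 4) and the other auxin libraries 604 ± 88.5 (n = 7), a difference of -323 (exact p 0.00303). Covered length was 695 ± 135 kb against 1357 ± 374 kb (difference -662 kb, exact p 0.0182). With equal list lengths the difference was -33.9 kb (exact p 0.594). With h1D-h2D Sen1-AID alone it was -562 kb (exact p 0.139), with h1D-h2D Top1-AID alone -762 kb (exact p 0.0556), and without h1D-h2D Top1-AID replicate 2 it was -601 kb (exact p 0.05). Median peak width was 1843 ± 308 bp and 1887 ± 344 bp (difference -43.7 bp, exact p 0.815).

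Region by region, the peaks at ADK1 with HTA1 and HTB1 (IV 913401–917652), RPL36B (XVI 73646–77075), NRD1 (XIV 171870–175211), RPP0 (XII 805197–807493) and IPP1 with HHT1 and HHF1 (II 253719–258290) were present in all 7 other libraries and in none of the combined mutants. So were those at PRE6 with RPS15 and RPP2A, SER1 with RPS30B and SNR36, RPS1A, YIL177C and SRL1. NRD1 encodes a partner of Sen1 in ending transcription. Of 853 regions, 99 were in all 11 libraries, and 73 were in all 7 others and in no combined-mutant library. No region showed the reverse. At an unadjusted p under 0.05, 198 regions were less often present in the combined mutants and 1 was more often present, at ADR1 and RAD9 (IV, 3 of 4 libraries against 0 of 7). With every list shortened to 254 peaks, 25 regions were less often present and 23 more often. At the adjusted threshold 73 were less often present (adjusted p 0.0354) and 0 more often. With the replicate number as a block 0 were less often present, but a block allows fewer arrangements and so raises the smallest p. The count of 73 became 0 when WT replicate 1, WT replicate 2 or either h1D-h2D library was left out. It was 121 without Sen1-AID replicate 2. Without 1 of those WT or h1D-h2D libraries, 4 against 6 allow a p of 0.00476 at best. There 73 or 74 regions had it, with 81 or 82 needed to pass. The count was also 0 without any of the 4 combined-mutant libraries, where 3 against 7 allow a p of 0.00833 at best. There 82 to 89 regions had it, with 141 or 142 needed to pass. So these values of 0 do not show that the pattern was lost.

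As shares of each list, peaks on ribosomal protein genes were 21.0% in the combined mutants and 19.5% in the others, and those on tRNA genes 35% and 35.4%, within the spread in both cases. Shares that rose past the adjusted threshold were those of Ty elements (6.04 ± 1.96% against 3.14 ± 0.759%, n = 4 and 7, exact adjusted p 0.0242), long coding genes (14.1% against 9.87%), snoRNA and snRNA genes (12.8% against 9.83%) and glycolytic and elongation genes (4.84% against 3.24%). Shares on subtelomeres fell from 5.29% to 1.67%, on Y prime helicase genes from 1.31% to 0.266%, and on the Nrd1-Nab3-Sen1 regulated genes from 0.787% to 0.169%. Of the 240 long coding loci 34 are Ty loci, and with repeated loci and chromosome ends left out long coding genes and snoRNA genes were no longer past the threshold. The 7 of 20 lists became 0 without h1D-h2D Top1-AID replicate 2. With equal list lengths the share on ribosomal protein genes reversed to -12.6 percentage points (exact adjusted p 0.0505), that on tRNA genes to 11.04 (0.149), that on glycolytic genes to -1.20 (0.0242) and that on snoRNA genes to -2.54 (0.113).

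RNase H genotype asks what the loss of RNH1 and RNH201 does across backgrounds. In h1D-h2D itself 131 ribosomal protein genes were covered in both libraries, against 133 in WT, and 214 tRNA genes, against 226. Over all 6 libraries without RNase H the peak number was 390 ± 169, against 604 ± 107 in the 5 with it (difference -214, exact p 0.0433). At the stricter score limit the difference was -164 (exact p 0.104). The call also ended with the replicate number as a block, though those numbers are not shown to pair the libraries. Of these groups, h1D-h2D alone had a mean of 606 peaks, against 641.5 in WT, and the combined mutants 295.5 and 268. Covered length differed by -482 kb (exact p 0.0758). The p for peak number lay between 0.0238 and 0.0905 when libraries were left out in turn. The difference between the Sen1 depletion effects with and without h1D-h2D was -262 peaks (exact p 0.278) and -364 kb (exact p 0.833), where the smallest possible p is 0.0556.

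Sen1 depletion alone asks where Rad52 goes when the helicase is missing. Both Sen1-AID libraries had peaks that WT lacked at NUP188 with SNR85 and CAC2 (XIII 66472–68357), at PDX3 with HMT1, SNR161 and TLC1 (II 305722–307697), at the Ty locus YML045W, at THG1 and at AVL9. The first 2 of these regions hold snoRNA genes, and TLC1 encodes the telomerase RNA. The other 3 hold tRNA genes. In WT 17 regions were present that both Sen1-AID libraries lacked, a number that rose to 144 without Sen1-AID replicate 1, to 33 without either WT library and to 29 without Sen1-AID replicate 2. Sen1-AID replicate 2 had the shortest list outside the combined mutants, and without it the new regions numbered 89. The Jaccard index between the Sen1-AID libraries was 0.364, against 0.674 between the WT libraries.

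At snoRNA genes the peaks of Sen1-depleted libraries reached further downstream, by a measure added after the data were examined. At SNR128 (X 139566–139691) the peak ended 815 and 769 bp past the gene in WT and 4149 and 1567 bp past it in Sen1-AID. SNR69, SNR64, SNR30 and SNR43 had the same direction, with 4924, 4195, 3758 and 3429 bp in Sen1-AID replicate 1 against 790, 726, 851 and 756 bp in WT replicate 1. In Sen1-AID replicate 2 the values were smaller, at 1488, 1182, 1249 and 1170 bp, against 777, 646, 717 and 684 bp in WT replicate 2. Of 62 snoRNA and snRNA genes measured in both groups, 41 had a longer downstream reach in both Sen1-AID libraries than in both WT libraries. A shorter one was seen at 5. Genes of a cluster can share a peak and were counted apart, so these are not independent sites. SNR72 to SNR78 each had the same mean difference of 75.5 bp. SNR78 reached 1944 bp in Sen1-AID replicate 2, against 1939 bp in WT replicate 1. Outside coding genes the median downstream reach was 1509 ± 193 bp in the 4 Sen1-depleted libraries and 801 ± 54.2 bp in the other 7 (exact p 0.00303, adjusted 0.0208). The median upstream reach there was 666 ± 103 bp and 740 ± 140 bp (exact p 0.412).

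The combined mutants differed in peak position at ribosomal protein and other coding genes. At ribosomal protein genes the median peak midpoint lay 779 and 648 bp downstream of the gene midpoint in h1D-h2D Sen1-AID. It lay 217 and 293 bp downstream in h1D-h2D Top1-AID, and at -63.5 and -3.5 bp in WT. These medians rest on 58 genes in each h1D-h2D Sen1-AID library, 72 and 60 in h1D-h2D Top1-AID, and 133 and 134 in WT. Over the combined mutants the upstream reach differed by -677 bp (exact adjusted p 0.0264), the downstream reach by 278 bp (0.168). The downstream reach was 1442.5 and 1167 bp in h1D-h2D Sen1-AID, 682 and 585.5 bp in h1D-h2D Top1-AID, and 760 and 706 bp in WT. So in h1D-h2D Top1-AID the offset came from a shorter upstream reach. Peaks that overlapped only the 3′ end made up 43.8 ± 17.8% of ribosomal protein genes with 1 peak in the combined mutants (n = 4) and 3.50 ± 8.92% in the others (n = 7, exact p 0.00606, adjusted 0.0182). This share was 58.6 and 51.7% in h1D-h2D Sen1-AID and 18.1 and 46.7% in h1D-h2D Top1-AID. It was 23.7% in Sen1-AID replicate 2, with 0 of 132 in replicate 1, and 12.2 and 1.55% in Gal-HO galactose. In h1D-h2D Top1-AID, Sen1-AID and Gal-HO galactose the higher value came from the replicate with narrower peaks (median 1400, 1375.5 and 1550.5 bp). But h1D-h2D replicate 2 had 0.758% at 1505 bp, and h1D-h2D Sen1-AID had medians of 2043 and 2061 bp. A role of peak width was not tested. Long coding genes without Ty had peaks on the 3′ end only at 70.4% against 53.6% (exact adjusted p 0.0182). The values were 82.9 and 76.9% in h1D-h2D Sen1-AID, 61.9 and 60% in h1D-h2D Top1-AID, and 61.3% in Top1-AID alone. At glycolytic and elongation genes the midpoint lay 437 bp further downstream in the combined mutants (exact adjusted p 0.0208).

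**Figure D3:**
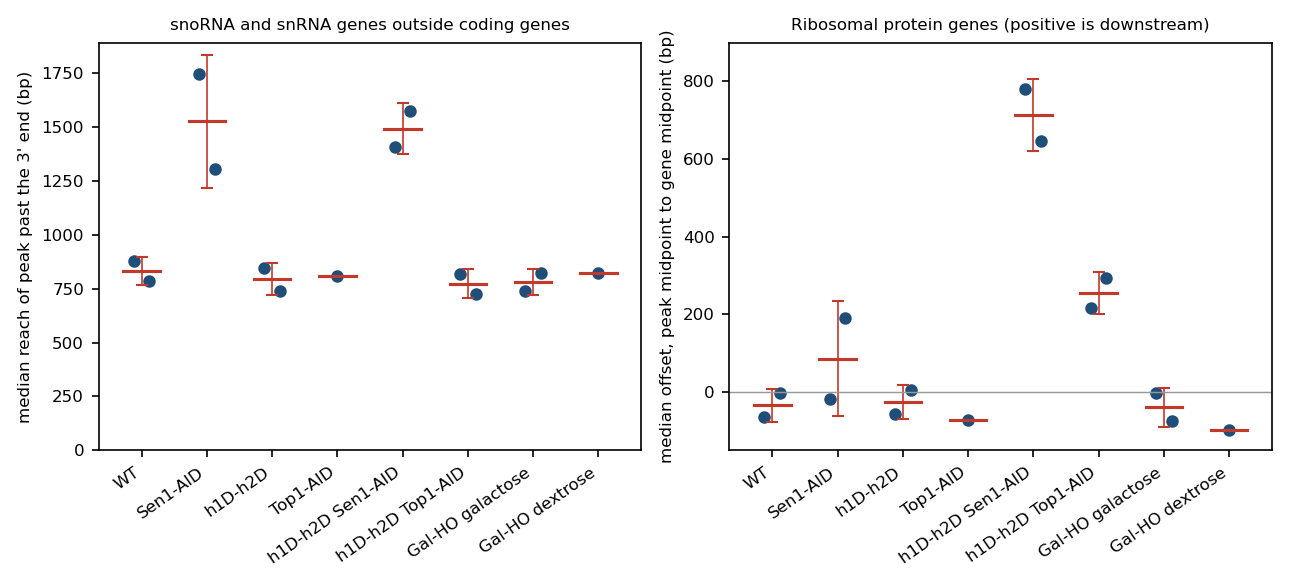
Median reach of Rad52 peaks past the 3′ end of snoRNA and snRNA genes outside coding genes (left, bp) and median distance from gene midpoint to peak midpoint at ribosomal protein genes (right, bp, positive is downstream). Points are libraries, red bars are group means and whiskers are 1 SD where a group has 2 libraries; on the left the Sen1-AID and h1D-h2D Sen1-AID libraries average 1509 bp and the other auxin libraries 801 bp.

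Removing RNase H and Sen1 together asks whether each covers for the other. New peaks appeared at SPT16 and CHC1 (VII 100369–103884), FLO11 (IX 390943–392909), CDC60 (XVI 249018–252370), RPN2 and THS1 (IX 213381–219595), and UTP10 and CCT7 (X 208205–213842). The next were at CHS3 and FUR4, PDR12, FPS1, and CHO2 and NSR1. SPT16 and FLO11 had the highest mean percentiles, 80.8 and 80.5. In total 33 regions were in both h1D-h2D Sen1-AID libraries and in neither WT library, and 25 of them were in no other group. None of the 33 overlapped a ribosomal protein, tRNA, snoRNA or snRNA gene, and 11 overlapped a long coding gene. New regions lack WT peaks by definition, and most genes of the first lists carried one. At least 1 WT library covered 134 of 138 ribosomal protein, 251 of 275 tRNA and 76 of 82 snoRNA and snRNA genes. For long coding genes it was 74 of 240, so the absence of the 33 regions from the first lists was nearly set in advance. In 25 regions the peak covered only the 3′ end of its most covered gene, in 0 only the 5′ end, in 5 both ends and in 1 the inside (sign test, exact p 5.96e-08), while 2 Ty regions were not classed. At the stricter score limit 5 regions were new, 3 of them over the 3′ end only and 0 over the 5′ end only. With equal list lengths 45 lay over the 3′ end only and 7 over the 5′ end only. Regions of WT absent from both libraries numbered 296, of which 101 overlapped tRNA genes and 55 ribosomal protein genes.

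**Figure D4:**
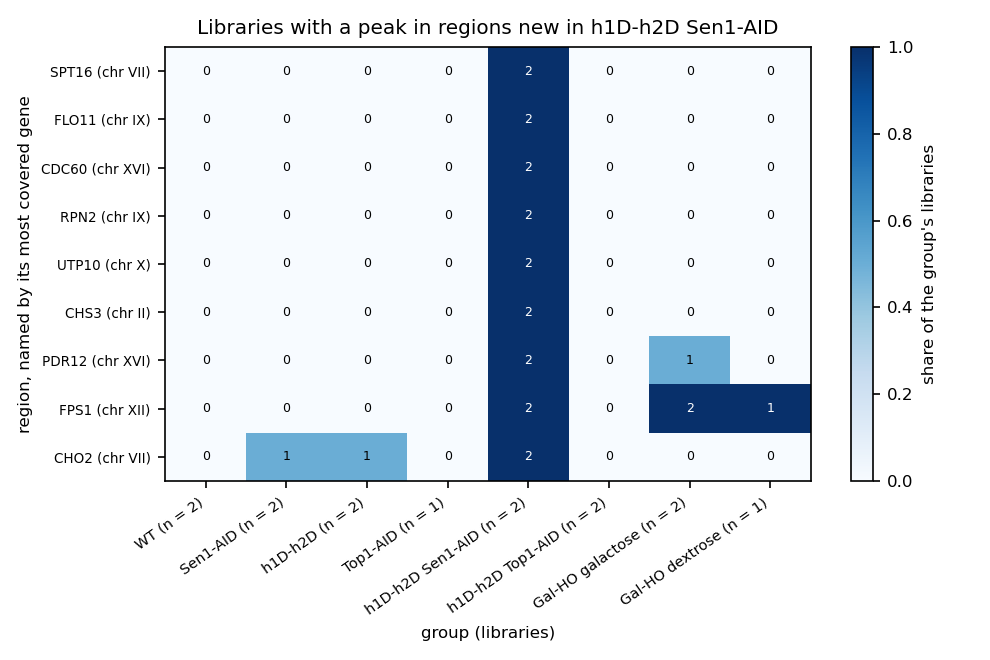
Number of libraries of each group with a peak in the 9 highest-scoring regions new in h1D-h2D Sen1-AID, ordered by mean score percentile. Columns are the 8 groups, the shade is the share of the group's libraries, and the rows of SPT16, FLO11, CDC60, RPN2, UTP10 and CHS3 are filled in the h1D-h2D Sen1-AID column alone.

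Removing RNase H and Top1 together gave 4 regions that WT lacked, a number that was 48 with equal list lengths, 12 with 5 kb bins, 1 without repeated loci and chromosome ends, and up to 15 with a library left out. The 4 were at HXT6 (IV 1158947–1160694) and the Ty loci YOL103W-B, YPR137C-B and YPR158W-B. Ty elements were overlapped by 17 of the 208 regions shared by both libraries, against 4.42 at random (permutation p 0.0002, the smallest possible, adjusted 0.000941). Subtelomeres were overlapped by 2 regions against 11.9 at random (adjusted p 0.00183), and in h1D-h2D Sen1-AID by 3 against 12.9 (adjusted p 0.00574). WT regions absent from both h1D-h2D Top1-AID libraries numbered 285.

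The combined mutants lost different strong sites. YEF3, TEF2, RPL28, PDC1 and FBA1 lost their peaks in both h1D-h2D Sen1-AID libraries and kept them in both h1D-h2D Top1-AID libraries. RPS1B did the reverse and is named here after its values were seen. Of 62 WT regions at or above the 90th percentile, 19 were absent from h1D-h2D Sen1-AID and 4 from h1D-h2D Top1-AID. With 17 lost only in the former and 2 only in the latter, the exact McNemar p was 0.000729. The call ended at the stricter score limit (p 0.289) and with equal list lengths (p 0.219), where in each case 4 more were lost in the former. The mean Jaccard index between libraries of the combined mutants was 0.251, against 0.608 and 0.544 between their own replicates.

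In h1D-h2D, HXT6 (IV 1158876–1160807), FLO5, ENO1, FLO1, BAP3, a region without a gene (V 5830–7003), CUE5 with SNR62, YML045W and YPT32 were the 9 regions in both h1D-h2D libraries and not in WT. Of these, HXT6 had the highest mean percentile, 47.8. WT regions absent from both numbered 20. The 9 became 27 and 18 without WT replicate 1 or 2, 19 and 24 without h1D-h2D replicate 1 or 2, and 4 at the stricter score limit. The 20 became 34 and 61 without WT replicate 1 or 2, 61 without h1D-h2D replicate 1, and 8 at the stricter score limit. For Top1-AID, with 1 library, IDH2 (XV 579411–581983), MRP20, LAF1, the Ty locus YNL054W-B, GND1, ENO1, MIG2, TRR1, CCW14 and CPA1 were the highest-scoring of 13 new regions. Top1-AID covered 171 of 275 tRNA genes, against 239 ± 13.4 in WT (n = 2). Of its 84 absent WT regions, 55 overlapped a tRNA gene. Top1-AID had 160 of 551 peaks on tRNA genes (29.0%, 95% Clopper-Pearson interval 25.3 to 33.0%).

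The HO strains are a control in which a break is expected at a known place. No library had a peak over MATALPHA1 or MATALPHA2. The genome build holds these alpha genes at MAT, and the labels do not give the mating type. In a strain without them part of this sequence could be missing. Reads from stretches that the mating-type loci share could still lie there, so mating type alone would not rule out a peak. Whether HO cut was not measured. So the control showed no Rad52 peak at MAT, for a reason that is not settled. The nearest galactose peaks began at III 215326 and 216967, which is 14356 and 15997 bp from MATALPHA1. HMLALPHA1 and HMLALPHA2 were fully covered in both galactose libraries (III 11465–14073 in replicate 1, percentiles 99.9 and 97.3) and in no dextrose peak. HMRA2 was fully covered in both galactose libraries as well, and also carried peaks in WT. Within 50 kb of MAT, peaks covered 14.1 ± 1.48 kb in galactose (n = 2) and 8.96 ± 3.0 kb in the other 12 libraries (one-sided exact p 0.0440). Dextrose had 9.36 kb and WT replicate 1 had 15.0 kb. Within 10 kb the difference was -0.425 kb, and with equal list lengths -1.16 kb. Leaving out either galactose library gave 4.10 or 6.195 kb with exact p of 0.231 or 0.0769, where 0.0769 is the smallest that 1 library against 12 can give.

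**Figure D5:**
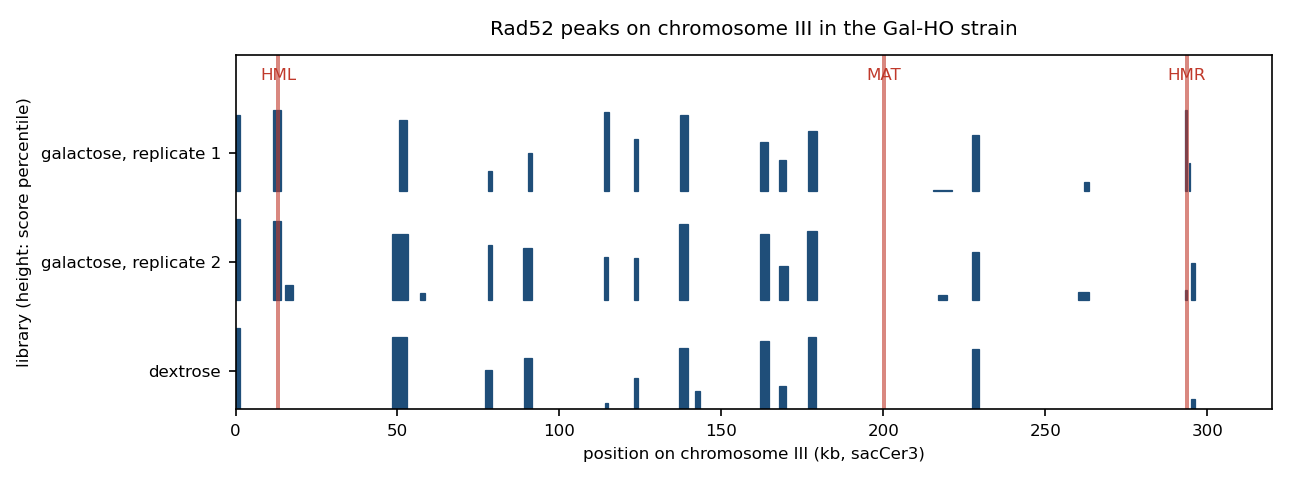
Rad52 peaks along chromosome III (kb, sacCer3) in the 3 Gal-HO libraries, with the mating-type loci HML, MAT and HMR in red. Box height is the score percentile within the library; HML lies under peaks at percentiles 99.9 and 97.3 in galactose and under none in dextrose, and MAT lies under none.

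Peaks at genes of sugar use and mating differed between galactose and dextrose. GAL2 (XII 288709–292915, mean percentile 99.7), GCY1 (XV 550273–553021, 92.5), GAL7 and GAL80 had peaks in both galactose libraries and not in dextrose. GAL1, GAL10, GAL3, MTH1 and PGM2 had peaks in both sugars and GAL4 in neither. Galactose genes were overlapped by 7 of the 493 regions shared by the galactose libraries, against 1.43 at random (permutation adjusted p 0.0064). The HO gene (IV 46271–48031) was fully covered in galactose, at percentiles 99.9 and 100, and 39.4% covered in dextrose. The galactose region over HO and SSB1 (IV 45359–48332) was also overlapped by a peak in 10 other libraries, dextrose included. Whether reads on HO came from this gene or from an added copy that makes HO was not examined. STE2, BAR1, AGA2 and MFA2, 4 of 7 a-specific genes in a list written after the data were examined, had a peak in both galactose libraries and not in dextrose (2 of 7 at the stricter score limit and 2 with equal list lengths), as had 73 of 6002 coding genes, these 4 included. These 4 also had peaks in both WT libraries, both h1D-h2D libraries and Top1-AID. Sen1-AID had them in both libraries except for AGA2, in 1, and STE2 had a peak in all 4 combined-mutant libraries, so the dextrose library was the only 1 of 14 that lacked all 4. STE6, also a-specific, had a peak in both sugars (percentiles 31.1 and 32.2 in galactose, 45.8 in dextrose). Of 12 pheromone response genes AGA1 and SST2 had a peak in both galactose libraries alone of all groups, and FUS3 and FIG1 had it in dextrose alone. Of 4 alpha-specific genes MF(ALPHA)1 had a peak, in dextrose alone (percentile 95.1). In total 37 regions were in both galactose libraries and not in dextrose, and 58 the reverse. Without galactose replicate 1 the 37 became 78, and without replicate 2 it became 59 and the 58 became 159.

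The edited genes themselves carried few peaks. RNH1 and TOP1 had none in any library. In the h1D-h2D strains, read here as lacking RNH1 and RNH201, the absence of a peak on these genes says nothing. RNH201 was touched over 76 and 87 bp in h1D-h2D Sen1-AID by the edge of a peak centred on LAT1 (XIV 491165–494762). That is 8.23 and 9.42% of a gene read as deleted, and whether the deletion includes this stretch was not examined. SEN1 was touched over 343 bp in Sen1-AID replicate 1, and in replicate 2 the nearest peak lay 1993 bp away.

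On average, replicates resembled each other more than libraries of different groups did. The mean Jaccard index was 0.573 within and 0.380 between groups over 14 libraries (permutation p 0.00132), and 0.564 and 0.386 over the 11 auxin libraries (permutation p 0.0122). As a share of peaks the difference over the auxin libraries was 0.0447 (permutation p 0.0859). Several groups did not follow the average. The Sen1-AID libraries resembled each other less (0.364) than they resembled WT (mean 0.535), h1D-h2D (0.527) or Top1-AID (0.514). WT and h1D-h2D libraries resembled each other (0.681) as closely as the WT libraries did (0.674), and Top1-AID resembled WT (0.687) as closely. The galactose libraries resembled dextrose (0.645) about as closely as each other (0.620).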

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

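All tests of explanations in this part were chosen after the results were seen, except the count of other splits of the libraries. Peaks on the mitochondrial chromosome numbered 3 in h1D-h2D replicate 1, 2 in WT replicate 1 and 0 in the other 12 libraries. They stand out because that chromosome entered no comparison and h1D-h2D replicate 1 lay above WT. The other h1D-h2D library had 0, and no explanation was tested.

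Fewer ribosomal protein, tRNA, snoRNA and histone genes carried a peak in the combined mutants, though with equal list lengths more tRNA genes did (by 28.3). Of the 330 splits of the 11 libraries into 4 and 7, 100 were examined, the real one included. The real split gave 199 regions past the unadjusted threshold and the highest of the other 99 gave 50, so 1 of 100 splits gave as many. Most of these splits separate replicates and mix short lists with long ones. They therefore cannot exclude a cause that goes with strain, batch or list length. In h1D-h2D Top1-AID the WT regions that were lost had lower scores than those kept, by a median of -40.0 percentile points, and in h1D-h2D Sen1-AID by -23.2 points. So weaker enrichment or lower depth could account for the shorter h1D-h2D Top1-AID lists and for the weaker regions lost in h1D-h2D Sen1-AID, and depth is unknown. As the whole account of h1D-h2D Sen1-AID it is argued against, because strong sites such as YEF3, TEF2 and PDC1 vanished there and stayed in h1D-h2D Top1-AID (exact McNemar p 0.000729), and because its new regions were a larger share of its shared regions (13.7% against 1.92%, Fisher's exact p 3.02e-06). The excess of lost strong sites was no longer past the threshold with equal list lengths (p 0.219) and at the stricter score limit (p 0.289). The new regions, 33 against 4, numbered 79 against 48 with equal list lengths (shares 14.4 percentage points apart, still past the threshold) and 5 against 2 at the stricter score limit (2.33 points apart, p 0.706), so neither argument holds at the stricter score limit. A redistribution of Rad52 towards the 3′ ends of genes such as SPT16 and CDC60 when RNase H and Sen1 are both missing may be present, as a hypothesis found and tested on the same data. The number of new regions over the 3′ end only, 25, was 3 at the stricter score limit and 45 with equal list lengths, where 7 lay over the 5′ end only, so its size is not settled.

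Peaks at snoRNA genes extended downstream in Sen1-depleted libraries. Wider peaks in general would also reach further upstream, but the upstream difference at all snoRNA and snRNA genes was -105 bp. A shift of equal size at every short gene is argued against, because tRNA genes moved by 63.9 bp against 380 bp at snoRNA genes. The tRNA offset itself passed the threshold (exact p 0.00606, adjusted 0.0264), as did the downstream reach there, longer by 136 bp (adjusted 0.0448), so a smaller general shift downstream stays open. The downstream reach outside coding genes was longer by 708 bp. At the 8 snoRNA genes inside coding genes the downstream reach differed by -142 bp. Of these 8 genes, 3 had a single peak in each h1D-h2D Sen1-AID library. By offset, peaks at the genes inside coding genes lay 194 bp further downstream (exact p 0.176), against 403 bp outside coding genes. The upstream reach inside differed by -343 bp (exact p 0.239). So few genes cannot decide whether the shift is absent inside coding genes. Transcription that runs past snoRNA ends without Sen1 is a candidate explanation for the larger part at snoRNA genes, which RNA data would have to test.

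The a-specific genes STE2, BAR1, AGA2 and MFA2 had peaks in both galactose libraries, and also in WT, h1D-h2D and Top1-AID, and lacked them in the single dextrose library. For these 4 genes the difference is an absence in dextrose, while other genes of the mating lists went both ways: AGA1 and SST2 had peaks in galactose alone, and MF(ALPHA)1 (percentile 95.1), FUS3 and FIG1 in dextrose alone. Lower sensitivity of the dextrose library would not give the 3 peaks in dextrose alone. For the 4 absent peaks it stays open. Sites lost to it should be the weaker ones, but in galactose the median of the 4 genes lay 8.38 percentile points above that of the 822 coding genes covered in all 3 Gal-HO libraries (permutation p 0.569), and 4 genes are too few to decide. The higher rate among a-specific genes than among all coding genes (Fisher's exact p 6.86e-07) decides nothing, because the list was written after the peaks had been seen. The dextrose list, with 637 peaks, was no shorter than either galactose list. The galactose libraries also covered 4 more galactose genes than dextrose, which the sugar could give in any strain. So another strain or mating type among these libraries cannot be told apart from an effect of HO. Dextrose itself covered 5 of 10 galactose genes, against group means of 0 to 2 in the auxin libraries, a difference whose cause was not tested. STE6, also a-specific, kept its peak in dextrose, so the absence does not cover the whole list. Neither transcription nor mating type was measured, and no biological explanation was tested. The peak at HML may also hold reads from MAT, since those loci share sequence, and read placement was not examined.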

How the results depend on the processing

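The alternatives named in processing were fixed before the data were examined. The results on list members covered, peak position and reach, ends of new regions, strength of lost regions, share of new regions and a-specific genes were chosen after the data were examined, and so were their alternatives. Peak number has no value under equal list lengths, which fix it. Values of single named genes and regions, the enrichment of single lists against random placement and the agreement of single group pairs were not run under alternatives. The difference of -323 in peak number kept its direction and its side of the threshold under every alternative run, at -348 to -302 with each library left out. The longer offset at snoRNA genes in Sen1-depleted libraries (380 bp) kept both under each library left out, at 353 to 406 bp, and so did the longer downstream reach outside coding genes (708 bp), at 629 to 775 bp with a library left out and 631 to 793 bp under 4 other settings. Among results that answer a comparison, 183 alternative values other than leave-outs changed neither direction nor call, 40 counts or values moved, 5 reversed and 13 lost a call. With libraries left out, 501 changed neither, 41 moved, 4 reversed, 21 lost and 2 gained a call. Among single lists and peak positions, 230 values changed neither, 3 moved, 31 reversed, 72 lost and 4 gained a call, and with libraries left out 647 changed neither, 3 moved, 8 reversed, 63 lost and 7 gained a call. New regions of h1D-h2D Sen1-AID over the 3′ end only, 25, numbered 3 to 45 under other settings and 25 to 41 with libraries left out, and those over the 5′ end only, 0, numbered 0 to 7 and 0 to 2. Unless a cause is given, the cause was not tested.

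Equal list lengths leave every library with 254 peaks, which removes few peaks of the combined mutants and most of the others. Covered length became -33.9 kb (p 0.594). Regions less often present in the combined mutants fell from 198 to 25 unadjusted and from 73 to 0 adjusted, and regions more often present rose from 1 to 23. Regions new against WT became 20 in Sen1-AID, 28 in Top1-AID, 79 in h1D-h2D Sen1-AID and 48 in h1D-h2D Top1-AID. WT regions missing became 9 in h1D-h2D, 23 in Top1-AID, 81 in h1D-h2D Sen1-AID and 59 in h1D-h2D Top1-AID, and dextrose regions missing with galactose 33. The difference near MAT reversed to -1.16 kb and the interaction for covered length to 131 kb. Shares reversed for glycolytic genes (-1.20 percentage points), ribosomal protein genes (-12.6), cell wall repeat genes (-0.394), pumps and permeases (-0.0141), tRNA genes (11.04) and snoRNA genes (-2.54). Members covered reversed for hexose transporters (0.679), pumps and permeases (0.214), tRNA genes (28.3), Ty elements (11.2) and long coding genes (13.8). The offset at long coding genes, Ty included, reversed from 684 to -357 bp. The longer downstream reach at tRNA genes was 155 bp (p 0.0576), snoRNA genes with a longer reach in Sen1-AID numbered 27, strong regions lost in h1D-h2D Sen1-AID alone exceeded those lost in h1D-h2D Top1-AID alone by 4 (p 0.219), and a-specific genes missing in dextrose numbered 2.

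At the stricter score limit, the difference of median width reversed to 106 bp. Regions less often present numbered 109 unadjusted and 0 adjusted, and lists whose share differed numbered 4. New regions numbered 1 in Sen1-AID, 4 in h1D-h2D, 4 in Top1-AID, 5 in h1D-h2D Sen1-AID and 2 in h1D-h2D Top1-AID, and WT regions missing in h1D-h2D numbered 8. The difference near MAT was 0.396 kb (p 0.451) and that of RNase H genotype -164 peaks (p 0.104). Shares reversed for ribosomal protein genes (-3.03) and hexose transporters (-0.448), and the offset at long coding genes reversed to -379 bp. At the same limit the excess of strong regions lost was 4 (p 0.289), the share of new regions differed by 2.33 percentage points (p 0.706), and 2 a-specific genes were missing in dextrose. With repeated loci and chromosome ends left out, 2 list shares differed. Of the 7, Ty elements, subtelomeres and Y prime helicase genes are removed or emptied by this step, and snoRNA genes and long coding genes lost their call. WT regions missing in h1D-h2D were 12 and regions new in h1D-h2D Top1-AID 1, the share on seripauperin and COS genes reversed to 0.0438, and the offset at long coding genes to -458 bp. With 5 kb bins, 4 regions were more often present, and new regions numbered 8 in Sen1-AID, 62 in h1D-h2D Sen1-AID and 12 in h1D-h2D Top1-AID. With peak midpoints, 3 list shares differed, and shares reversed for ribosomal protein genes (-4.09) and pumps and permeases (-0.0510). Agreement among auxin libraries as a share of peaks was 0.0447 (p 0.0859). Around MAT, 10 kb gave -0.425 kb and 100 kb gave 1.64 kb (p 0.352).

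Each combined mutant alone leaves 2 libraries against 7, which raises the smallest p, to 0.0278 in the test of regions, where too few regions had that p for any to pass the adjusted threshold. With h1D-h2D Sen1-AID alone, covered length differed by -562 kb (p 0.139) and median width by 165 bp, reversed. Regions more often present numbered 28, regions less often present at the adjusted threshold 0, and list shares that differed 0. Shares reversed for ribosomal protein genes (-0.751), hexose transporters (-0.127) and pumps and permeases (-0.214). With h1D-h2D Top1-AID alone, covered length differed by -762 kb (p 0.0556), regions less often present numbered 124 unadjusted and 0 adjusted, and list shares that differed 0. The share of ribosomal protein genes with a peak on the 3′ end only differed by 28.9 percentage points (p 0.0556). Shares reversed for edited loci (-0.0195), stress genes (0.0288), histone genes (0.0158), cell wall repeat genes (-0.0330) and seripauperin and COS genes (0.182). Members covered reversed for edited loci (-0.143), hexose transporters (0.143), pumps and permeases (0.214) and Ty elements (2.43).

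With the replicate number as a block, the RNase H difference in peak number was -203 (p 0.065), regions more often present numbered 2, and regions less often present at the adjusted threshold 0, from 73. The deviations of libraries with the same number correlated at 0.00026 to 0.305 over 10 group pairs, and 3 of these exceeded 0.1, among WT, Sen1-AID and h1D-h2D, so the numbers are not shown to pair the libraries.

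Leaving out each library in turn gave these ranges. Covered length differed by -761 to -571 kb, losing its call (p 0.05) without h1D-h2D Top1-AID replicate 2, and median width by -129 to 104 bp. Regions more often present numbered 0 to 2, and regions less often present at the adjusted threshold 0 to 121. A 0 there says nothing about the regions. In each such case, with a WT, h1D-h2D or combined-mutant library left out, too few regions had the smallest possible p for any to pass. List shares that differed numbered 0 to 9. New regions ranged from 5 to 89 in Sen1-AID, 9 to 27 in h1D-h2D, 13 to 56 in Top1-AID, 4 to 15 in h1D-h2D Top1-AID and 37 to 78 in galactose. WT regions missing ranged from 17 to 144 in Sen1-AID, 20 to 61 in h1D-h2D and 84 to 138 in Top1-AID, and dextrose regions missing from 58 to 159. A group left with 1 library has fewer conditions to meet, which raises such counts. The difference near MAT ranged from 4.10 to 6.195 kb (p 0.0256 to 0.231). That of RNase H genotype ranged from -263 to -182 peaks (p 0.0238 to 0.0905) and from -636 to -350 kb (p 0.0238 to 0.171). The interaction for covered length ranged from -934 to 207 kb, reversed without Sen1-AID replicate 1. The share on seripauperin and COS genes ranged from -0.0739 to 0.0573 and that on tRNA genes from -1.49 to 1.45. Depth is unknown, and a peak missing from a list says only that it was not called.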

Other observations

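The measures in this part were chosen after the results were seen. SNR161 and TLC1, which share a region with PDX3 and HMT1, carried a peak in both Sen1-AID libraries and in no library of any other group. NRD1 carried a peak in all 7 auxin libraries outside the combined mutants and in none of the 4 within them. IMD3, 1 of the Nrd1-Nab3-Sen1 regulated genes, carried a peak in both Sen1-AID libraries and in neither library of either combined mutant.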
